A study of Arabidopsis thaliana with 8 samples.

How the data were processed

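RNA from leaves of Arabidopsis thaliana was hybridised to 8 Agilent 1-colour arrays, 4 from 35S::Rap2.9-GFP plants and 4 from wild-type Col-0 plants. The labels and the series design text, which calls the samples biological replicates, gave the genotype of every array. Per the labels, plants were 54 days old, the seeds had been kept for 3 days at 7 °C, and the plants then spent 20 days with 8 h of light at 22 °C. A further 34 days followed with 12 h of light and 12 h of dark at 22 and 18 °C, 60 µmol of light and 60% humidity, and 200 ng of RNA was labelled with the dye Cy3 for each array.

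Per the file headers, the scanner files hold the intensity of each spot, made by Agilent Feature Extraction 11.5.1.1 for array design 021169, with the processed signal background-subtracted and detrended within an array and not normalised between arrays. The value table deposited by the authors holds log2 values for 43663 probes. Its scale was found by comparison with the scanner files, since its normalisation is not given in the sources used here. In that table every probe was centred on its median over the arrays and every column had the same mean of 0.0165. The column medians were 0.0015, 0.0116, -0.0036 and 0.0041 for wild-type replicates 1 to 4 and -0.0146, -0.0040, -0.0025 and 0.0019 for transgenic replicates 1 to 4. Across probes, which are not independent replicates, Pearson's r between the table and the centred log2 scanner signals was 0.934 to 0.98 for 7 arrays and 0.582 for transgenic replicate 1.

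The main values were the log2 processed signal minus the 75th percentile of the same array. Of 45220 spots, 1417 were controls and were left out, as were 25 to 63 spots per array that the scanner software marked as outliers for non-uniformity or population. A probe was tested if it was well above background on at least 4 of the 8 arrays, whatever their genotype. This left 33147 of 43603 probes, and 10456 were below the filter. Probes were matched to loci through their RefSeq transcript names in the gene table, made for the assembly TAIR10.1. The match was found for 34348 probes and not for 9255, and unmatched probes were tested under their own transcript name or identifier. The array header names its build TAIR10 without the table's suffix, so no positions are given. A gene was represented by its brightest tested probe, which gave 25089 genes, 20268 of them with a locus name. Among 5971 loci with 2 or more tested probes, 12 had probes past the threshold in opposite directions and 1526 had some probes past it and others not.

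Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with version 1.17.8 of the package data.table to read the files, and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. For 32 gene lists fixed before the data were examined, camera in limma, which asks whether the genes of a list rank higher or lower than other genes, was run with its preset correlation of 0.01 on the 31 lists with at least 3 tested members. Camera with a correlation estimated from the arrays and fry, which asks whether a list's own genes move, were run beside it. Of 450 list entries, 9 were left out because the gene table gives only other names for their locus, and 412 were tested. The entries left out were UGT74C1, DVR, NAC092, YLS3, UGT75C1, 2CPA, GC1, TIP41 and SAND, while PRXIIE was kept as the 1 entry whose locus has no name in the table. The lists ending in markers, with the photosynthesis list for mesophyll, stand for other cells or organs that leaf samples could hold.

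The genes named were RAP2.9, then the 15 higher and the 15 lower genes with the largest log2 change among genes past the threshold that have a locus name and whose arrays do not overlap between genotypes. From each list, up to 4 members past the threshold with the largest change were added, or up to 2 with the smallest p where none passed. Other genes are said to have been chosen after their values were seen. Where no array of a genotype was well above background for a gene, its fold is given as a lower bound against the lowest signal well above background.

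The gene fit and camera were tested on simulated gene values for 24954 genes, so the scaling, filter and probe choice were not tested. Of 50 genes planted at each log2 change of 0.5, 1, 2 and 4, the fit recovered 25, 42, 43 and 47, and 8 of 165 calls were false. The planted genes were a far smaller share of all genes than the 34.6% called in the real data. A list planted with a shift was called, and 0 of the others were. The simulated genes varied independently of each other, so this did not test how camera treats lists whose genes vary together. The alternatives were another background correction (normexp, offset 50), quantile, median and restricted percentile scaling, the deposited value table, looser and stricter filters, outlier spots kept, other uses of a gene's probes, slide and replicate number as blocks, other variance models, each array left out, and stricter thresholds. The normexp offset is added to every signal and shrinks the log2 changes of dim genes by construction. The normexp alternative used the median spot signal because the files hold no mean signal. That choice, a floor under dim values, and list counts without transgenic replicate 1 were chosen after seeing the data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.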

Results

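Transcript levels were measured in leaves of 54-day-old Arabidopsis plants that carry 35S::Rap2.9-GFP and of wild-type plants. The transgene expresses RAP2.9, a transcription factor of the AP2/ERF family, fused to green fluorescent protein (GFP) from the strong viral 35S promoter. The wild type was Col-0, the standard laboratory accession. There were 4 arrays of each genotype, and their number limits the precision. Between 72.4% and 84.3% of probes were well above background per array, with the highest share on transgenic replicate 1. The 75th percentile of the signal ran from 1699 to 2576. Across probes, Pearson's r between arrays was 0.985 to 0.992 within the wild type, 0.98 to 0.993 within the transgenic group and 0.963 to 0.977 between them. The arrays were on 2 slides, each with 2 arrays of each genotype. The comparison asks which transcripts differ in leaves when RAP2.9 is overexpressed.

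The 2 probes for RAP2.9 (AT4G06746) moved in opposite directions. The probe with the higher mean rose 17.7-fold in the transgenic leaves, from a log2 signal over the array's 75th percentile of 1.69 ± 0.21 (SD, n = 4) to 5.83 ± 0.25 (SD, n = 4), with an adjusted p over all probes of 5.39e-06. The other probe fell 3.42-fold, from 1.60 ± 0.16 (SD, n = 4) to -0.17 ± 0.48 (SD, n = 4), with an adjusted p of 0.00115. The transgenic arrays lay above every wild-type array for the rising probe and under every wild-type array for the falling probe. Within the slides the rising probe changed by 4.28 and 4.00 and the falling probe by -1.48 and -2.07. Both probes were well above background on all 8 arrays. The probe sequences are not in the files, so their position relative to the transgene is unknown. The mean of both probes changed by 1.18.

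**Figure D1:**
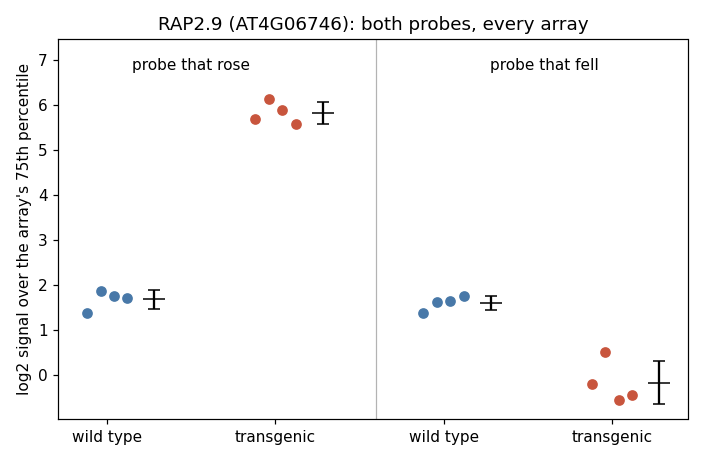
Log2 signal of both RAP2.9 probes over the array's 75th percentile (vertical axis) in wild-type and transgenic leaves, with 1 point per array and bars for the mean and SD of 4 arrays. The rising probe went from a mean of 1.69 to 5.83 and the falling probe from 1.60 to -0.17.

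In the transgenic leaves the galactinol synthase gene GOLS3 (AT1G09350), whose enzyme starts raffinose synthesis, fell 222-fold, with a log2 change of -7.79 ± 0.23 (SE, n = 4 per genotype). XTH6 (AT5G65730), which codes for an enzyme that remodels cell-wall xyloglucan, fell by 4.66 ± 0.16 (SE) on the log2 scale. The lipid transfer protein gene LTP4 (AT5G59310) rose by 4.55 ± 0.63 (SE) and the vegetative storage protein gene VSP2 (AT5G24770) by 3.82 ± 0.46 (SE). The largest fitted rise by the fixed rule was that of AT4G36850, 51.2-fold. Its order against AT2G37670, GLIP6 and AT3G11860 is not fixed, since most or all of their wild-type arrays were not well above background. Of 25089 genes tested, 4660 were higher and 4025 lower in the transgenic leaves, 34.6% of all, and 16404 did not pass. Among 20268 genes with a locus name, 4079 were higher and 3415 lower. The fitted log2 change was 1 or more for 1046 higher genes and -1 or less for 578 lower genes. These fits include genes with no array above background in a genotype, for which the fitted value is no bound.

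Other genes with large rises included MRD1 (AT1G53480), with a log2 change of 4.93 ± 0.29 (SE), AT3G07350, with 4.14 ± 0.46 (SE), and AT2G44240, with 3.88 ± 0.90 (SE). The lipase gene GLIP6 (AT1G71120) rose by 5.35 ± 0.26 (SE), AT2G37670 by 5.58 ± 0.52 (SE), the jacalin-type lectin gene JAL33 (AT3G16450) by 4.12 ± 0.68 (SE) and the sugar transporter gene SAG29, also SWEET15 (AT5G13170), by 4.66 ± 1.12 (SE). Each of these 4 was well above background on 1 of 4 wild-type arrays. The senescence-associated protease gene SAG12 (AT5G45890), also above background on 1 of 4 wild-type arrays, rose by 3.80 ± 1.13 (SE, adjusted p = 0.0359), a call lost in 5 of the 8 fits that each left out 1 array, with an adjusted p of up to 0.0837. Its other probe did not pass (log2 change 3.02, adjusted p = 0.133). No wild-type array was well above background for AT3G11860, AT5G45960 and AT4G15690, which were at least 9.44-fold, 5.85-fold and 7.95-fold higher. With normexp the calls of these 3 genes and of GLIP6, AT2G37670, JAL33, SAG29, SAG12 and AT2G44240 were lost.

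The dehydrin gene LTI30 (AT3G50970) fell by 4.00 ± 0.22 (SE) and LEA14 (AT1G01470), which codes for a late embryogenesis abundant protein, by 3.70 ± 0.11 (SE). AT2G35290 fell by 4.58 ± 0.34 (SE) and EXO (AT4G08950), a gene that brassinosteroid hormones induce, by 3.26 ± 0.21 (SE). AT2G16750, AT5G44565, AT3G06035 and AT2G13960 changed by -3.69, -3.49, -3.38 and -3.37. AT1G53633, AT5G46295 and the B-box gene BZS1 (AT4G39070) changed by -4.31, -3.90 and -3.35, with 3 of 4 transgenic arrays well above background. AT5G23950, above background on 1 of 4 transgenic arrays, changed by -3.63. GLTP2 (AT1G21360), above background on 0 of 4 transgenic arrays, was at least 2.03-fold lower. AT5G23950 and GLTP2 lost the call with normexp.

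With slide as a fixed block 4244 genes were higher and 3723 lower. Of 133 named genes, 9 lost the call with that block, among them SAG12 (adjusted p = 0.0518), RAV1, FUL, XCP2, CYP79F1, CYP71A12, FRK1 and BHLH100 (adjusted p = 0.0704). The arrays of the genotypes did not overlap for 9206 genes, 36.7%, where chance gives 2.86%. The share of higher genes among those past the threshold was 53.7%, and with median scaling it was 38.9%, with 3199 higher and 5016 lower. Without transgenic replicate 1, 3759 genes were higher and 3752 lower. The normexp background correction gave 1285 higher and 1499 lower genes, and 58 of 133 named genes lost the call with it.

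Genes of the cold and CBF regulon, which CBF transcription factors switch on in the cold, were lower. The list also holds CBF1, CBF2 and CBF3 themselves, which enter its median and camera test and were the only members not past the threshold as lower. Of 16 members tested, 13 fell, 1 rose and 2 did not pass, with 13 lower and 2 higher adjusted over the list alone. Besides GOLS3 and LTI30, KIN1 (AT5G15960) fell by 2.86 ± 0.12 (SE) and the dehydrin gene ERD10 (AT1G20450) by 2.69 ± 0.16 (SE). The member that rose was CBF3 (AT4G25480), by 1.53 ± 0.10 (SE), while CBF1 had a log2 change of 0.76 ± 0.30 (SE, adjusted p = 0.0846) and CBF2 of -0.02 ± 0.23 (SE, adjusted p = 0.945). These CBF genes were chosen after their values were seen. The list median was -1.61 (camera adjusted p = 6.2e-09), and adjusted p = 0.618 with an estimated correlation. Within the slides the median was -1.67 and -1.56.

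**Figure D2:**
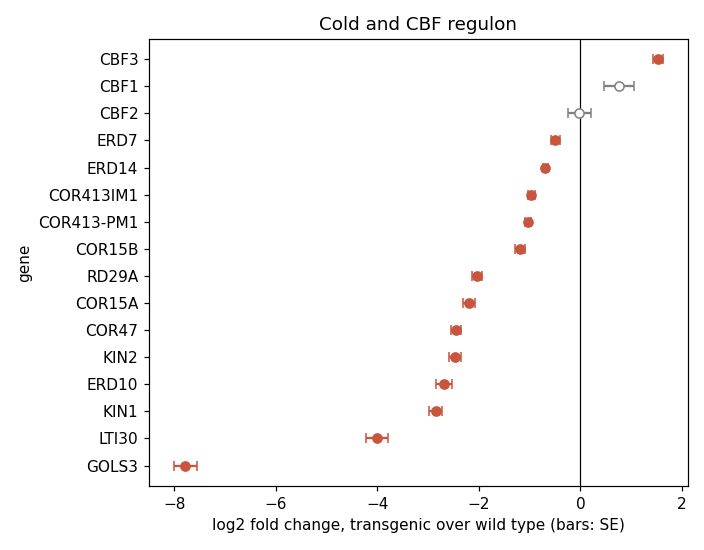
Log2 fold change (horizontal axis, transgenic over wild type) of the 16 tested members of the cold and CBF regulon, with SE bars, 4 arrays per genotype and filled points for genes past the threshold. GOLS3 at -7.79 and CBF3 at 1.53 mark the ends of the range.

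DREB factors are AP2/ERF proteins that bind drought and cold response elements, and RAP2.9 belongs to their A-5 subgroup. The list of DEAR and related A-5 DREB factors also holds DREB2A, DREB2B, TINY, DDF1 and RAP2.4, which belong to other DREB subgroups. Of its 12 tested members, 5 were lower, 2 higher and 5 not past the threshold, with 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.145, and 0.0446 with no filter on dim probes). RAP2.1 (AT1G46768) fell by 1.79 ± 0.05 (SE) and DEAR3 (AT2G23340) by 1.71 ± 0.09 (SE), while RAP2.10 (AT4G36900) was 2.45-fold and DREB26 (AT1G21910) 2.15-fold lower. DREB26 lost the call with normexp. The others past the threshold, chosen after their values were seen, were DEAR1 at -0.99, DEAR2 at 0.49 and RAP2.4 at 0.78.

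Genes of flavonoid and anthocyanin synthesis, the route to red and purple pigments, were higher. Of 17 tested, 12 rose, 1 fell and 4 did not pass, with 13 higher and 1 lower adjusted over the list alone. LDOX (AT4G22880) rose by 3.62 ± 0.41 (SE), chalcone synthase, CHS (AT5G13930), by 3.13 ± 0.29 (SE), TT7 (AT5G07990) by 3.06 ± 0.26 (SE) and DFR (AT5G42800) by 3.05 ± 0.41 (SE). The regulator MYB111, chosen after its value was seen and above background on 3 of 4 transgenic arrays, changed by -1.92. The list mean was 1.28 and the median 1.096 (camera adjusted p = 0.000144), and adjusted p = 0.618 with an estimated correlation.

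Genes of chlorophyll biosynthesis were higher, 12 of 15 tested and 13 adjusted over the list alone, and 0 were lower. GUN4 (AT3G59400), a regulator of magnesium chelatase, rose 2.47-fold, HEMA1 (AT1G58290) by 1.27 ± 0.11 (SE) on the log2 scale, PORA (AT5G54190) by 1.21 ± 0.16 (SE) and the magnesium chelatase gene CHLH (AT5G13630) by 1.06 ± 0.10 (SE). The brightest of 3 PORA probes gave that value, and the other 2 rose by 3.83 ± 0.30 (SE) and 3.93 ± 0.44 (SE). The median was 0.48 (camera adjusted p = 2.69e-05), and adjusted p = 0.618 with an estimated correlation. Of 23 photosynthesis genes, 3 were higher, LHCB2.1 by 1.03, PSAH2 by 0.51 and PSBO2 by 0.32, and 20 did not pass. PSBO2 lost its call with normexp. The other LHCB2.1 probe rose by 1.92, and 5 genes of the list were higher with quantile normalization and with the deposited value table. Adjusted over the list alone, 3 were higher (camera adjusted p = 0.796, but 0.0142 with quantile normalization, 0.0116 with the deposited value table and 0.0177 with the mean of a gene's probes).

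Genes of indole glucosinolate and camalexin synthesis, which make defence compounds from tryptophan, were higher, 10 of 13 tested and 10 adjusted over the list alone, and 0 were lower. CYP81F4 (AT4G37410) rose by 2.23 ± 0.12 (SE), CYP79B3 (AT2G22330) by 1.08 ± 0.14 (SE) and CYP79B2 (AT4G39950) by 1.06 ± 0.11 (SE). The change of CYP71A12 was 1.57 ± 0.49 (SE), a call lost in 7 of the 8 fits that left out 1 array and with normexp. The median was 0.79 (camera adjusted p = 0.000154), and adjusted p = 0.125 with an estimated correlation. For aliphatic glucosinolates, made from methionine, 4 of 15 genes were higher and 0 lower, and 8 were higher adjusted over the list alone. They were MAM3 (AT5G23020) at 0.60 ± 0.09 (SE), MYB28 at 0.51, BCAT4 at 0.63 and CYP79F1 at 0.62, of which the last 3 lost the call in 2, 6 and 6 of those 8 fits. MYB28 also lost it with normexp. The other CYP79F1 probe did not pass (0.27, adjusted p = 0.51). The median was 0.51 (camera adjusted p = 0.0074), and adjusted p = 0.669 with an estimated correlation.

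Of 20 genes of abscisic acid and drought response, 10 rose, 2 fell and 8 did not pass, with the same counts of 10 and 2 adjusted over the list alone. Besides LTP4, the proline synthesis gene P5CS1 (AT2G39800) rose by 2.59 ± 0.22 (SE) and the phosphatase gene HAI1 (AT5G59220) by 1.38 ± 0.27 (SE). LTP3 had a change of 1.38 and lost its call in 6 of the 8 fits that left out 1 array, and its other probe did not pass (adjusted p = 0.117). With normexp HAI1 and LTP3 did not pass. The members that fell, chosen after their values were seen, were RD29B at -0.78 and RAB18 at -0.47. The median was 0.45 (camera adjusted p = 0.00903), and adjusted p = 0.618 with an estimated correlation. Of 23 cuticle and wax genes, 10 rose, 2 fell and 11 did not pass, with 12 higher and 2 lower adjusted over the list alone. CER4 (AT4G33790), which makes wax alcohols, rose by 3.37 ± 0.30 (SE), KCS2 (AT1G04220) by 1.32 ± 0.09 (SE), CER1 (AT1G02205) by 1.24 ± 0.28 (SE) and LACS2 by 0.87. CER4 and KCS2 lost the call with normexp. The other CER1 probe did not pass (1.02 ± 0.58, SE, adjusted p = 0.211). CER3 at -0.23 and CYP86A2 at -0.54 fell and were chosen after their values were seen. The median was 0.40 (camera adjusted p = 0.0074), and adjusted p = 0.618 with an estimated correlation.

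Of 21 salicylic acid defence genes, 9 rose, 1 fell and 11 did not pass, with 10 higher and 2 lower adjusted over the list alone. The pathogenesis-related genes PR5 (AT1G75040), PR2 (AT3G57260) and PR1 (AT2G14610) rose by 2.52 ± 0.17 (SE), 2.01 ± 0.19 (SE) and 1.82 ± 0.38 (SE). The regulator WRKY18 (AT4G31800) fell by 1.85 ± 0.22 (SE). With normexp PR1 did not pass. The median was 0.61 (camera adjusted p = 0.0401), and adjusted p = 0.669 with an estimated correlation. The list did not pass without wild-type replicate 1 (adjusted p = 0.127), wild-type replicate 2 (0.0576), transgenic replicate 2 (0.0601) or transgenic replicate 4 (0.0819). It did not pass either with a filter on all 8 arrays (0.0645), with array weights (0.0652) or with a floor on dim values (0.0523).

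Among markers of other cells and organs, all 5 xylem and secondary wall markers were higher, and 5 adjusted over the list alone. The cellulose synthase genes IRX3 (AT5G17420) and IRX1 (AT4G18780) both rose by 1.24 ± 0.27 (SE), and IRX5, chosen after its value was seen, by 0.72. XCP1 at 1.35 and XCP2 at 0.89 lost the call in 6 and 7 of the 8 fits that left out 1 array. The median was 1.24 (camera adjusted p = 0.0379), and adjusted p = 0.669 with an estimated correlation. The call was lost without transgenic replicate 2 (adjusted p = 0.0695) and with normexp (0.0649), and without transgenic replicate 1 it held with 3 of 5 members higher. Of 3 root markers 2 were higher, PYK10 by 3.10 and NRT2.1 by 0.59, and 2 of 3 flower organ markers, SEP3 by 1.60 and AG by 1.27, with the same counts of 2 and 2 adjusted over the list alone (camera adjusted p = 0.203 and 0.24). Of 7 guard cell and stomatal lineage markers 4 were higher, MYB60 at 0.57, TMM at 0.55, KAT1 at 0.40 and FAMA at 0.38, and 5 adjusted over the list alone (camera adjusted p = 0.0644, but 0.0384 with median scaling, 0.028 with the filter on all 8 arrays, 0.0396 with no filter, 0.0483 with replicate number as a block, 0.0463 with slide added and 0.0492 without wild-type replicate 4). Of 6 phloem markers 2 were lower, SWEET11 at -0.61 and SWEET12 at -0.31, and 2 adjusted over the list alone (camera adjusted p = 0.0577, but 0.0172 with no filter, 0.0494 with the mean of a gene's probes, 0.0235 with replicate number as a block, 0.0264 with slide added, 0.0327 without transgenic replicate 3 and 0.0393 without transgenic replicate 4). None of the 5 trichome markers passed, nor did any adjusted over the list alone (0 by limma), with TRY at 0.17 (adjusted p = 0.118) and CPC at -0.19 (adjusted p = 0.18), and camera gave an adjusted p of 0.972. With quantile normalization TRY was at -0.18 and CPC passed at -0.28. None of the 5 seed markers was above the filter. KAT1, NRT2.1 and SWEET12 lost the call in 5, 5 and 3 of the 8 fits. Among these markers, XCP1, XCP2, IRX1, IRX3, PYK10, NRT2.1, SEP3, AG, MYB60, TMM, KAT1, FAMA and SWEET12 lost the call with normexp.

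**Figure D3:**
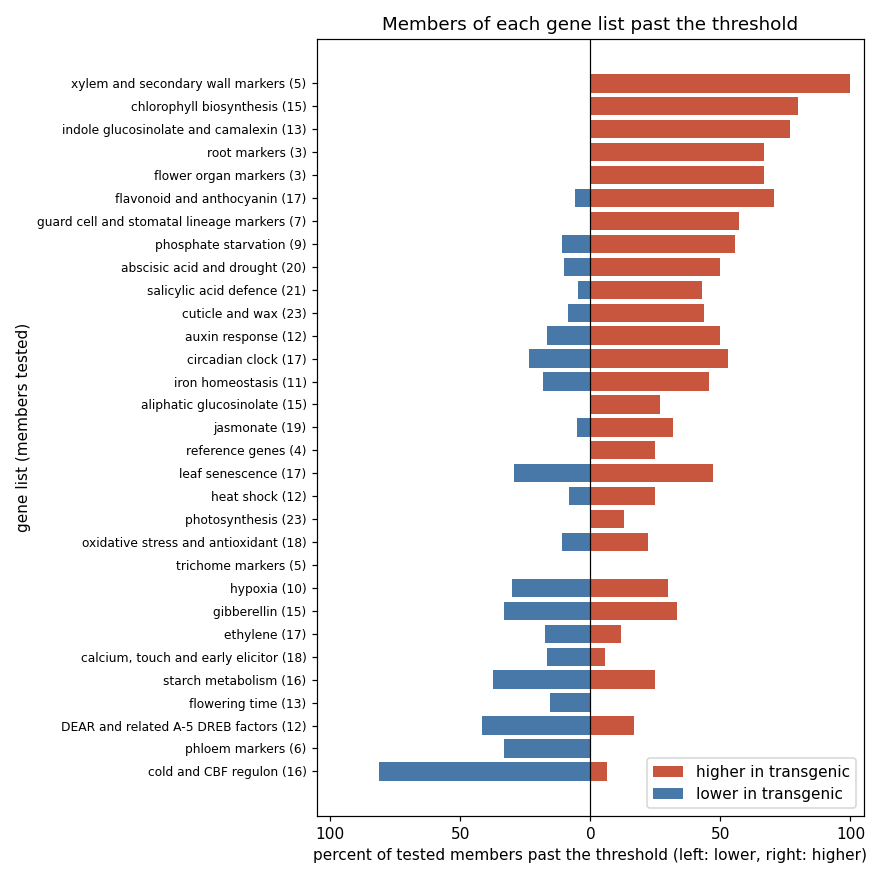
Percent of the tested members of each of 31 gene lists (horizontal axis) past the threshold as higher (right) or lower (left) in transgenic leaves, with the number of members tested in parentheses and 4 arrays per genotype. Of 16 cold and CBF regulon members 13 were lower, and all 5 xylem markers were higher.

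Genes of the circadian clock moved both ways. Of 17 tested, 9 were higher and 4 lower, with 10 and 5 adjusted over the list alone (camera adjusted p = 0.24). The morning genes CCA1 (AT2G46830) and PRR9 (AT2G46790) rose 2.3-fold and 2.31-fold, RVE1 rose by 1.35 ± 0.31 (SE), and the evening gene LUX (AT3G46640) fell by 1.09 ± 0.07 (SE). The others that fell, chosen after their values were seen, were TOC1 at -0.61, ELF3 at -0.42 and ELF4 at -0.92. Of 19 jasmonate genes 6 were higher, 1 lower and 12 not past the threshold, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.11). The list passed camera with quantile normalization (adjusted p = 0.0394) and the closely matching deposited value table (0.0386), with 7 members higher in both. It also passed with normexp (0.00117) and without wild-type replicate 4 (0.031). VSP1 (AT5G24780) rose by 3.70 ± 0.46 (SE), the defensin gene PDF1.2 (AT5G44420) by 2.78 ± 0.37 (SE) and THI2.1 (AT1G72260) by 2.72 ± 0.42 (SE), and OPR3, chosen after its value was seen, changed by -0.47. Of 17 leaf senescence genes 8 were higher and 5 lower, with 9 and 5 adjusted over the list alone (camera adjusted p = 0.674). SAG13 rose by 1.80 ± 0.37 (SE) and the nuclease gene RNS1 changed by -1.87 ± 0.51 (SE), a call lost in 2 of the 8 fits. Without transgenic replicate 1 the senescence counts were 5 and 3. CCA1, PRR9, RVE1 and RNS1 lost the call with normexp.

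Of 10 hypoxia genes 3 were higher and 3 lower, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.404). With quantile normalization and with the deposited value table, 3 were higher and 6 lower. PDC1 (AT4G33070) rose by 2.68 ± 0.18 (SE) and HB1 (AT2G16060) by 1.34 ± 0.19 (SE), while the sucrose synthase genes SUS1 (AT5G20830) and SUS4 (AT3G43190) fell by 1.76 ± 0.06 (SE) and 1.73 ± 0.09 (SE). ADH1 at 0.23 and HRE1 at -0.69 also passed and were chosen after their values were seen. Of 15 gibberellin genes 5 were higher and 5 lower, and as many adjusted over the list alone (camera adjusted p = 0.854), with GA2OX2 at -1.65, RGL3 at 1.41, GA2OX6 at -1.25 and GASA1 at -0.93. Of 12 auxin response genes 6 were higher and 2 lower, and as many adjusted over the list alone (camera adjusted p = 0.404), with GH3.3 at 2.07, IAA29 at -1.40, GH3.5 at 1.15 and IAA6 at -1.07. Of 16 starch metabolism genes 4 were higher and 6 lower, and as many adjusted over the list alone (camera adjusted p = 0.674), with GBSS1 at 0.83, PHS1 at 0.67, SEX1 at -0.55 and SEX4 at -0.53. GA2OX6 and IAA6 lost the call in 2 and 4 of the 8 fits that left out 1 array. PDC1, RGL3, GH3.5, IAA6 and SEX4 lost it with normexp.

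Of 9 phosphate starvation genes 5 were higher and 1 lower, and as many adjusted over the list alone (camera adjusted p = 0.14), with PAP17 at 1.26, MGD3 at -1.20, PPCK1 at 1.17 and PHO1;H1 at 0.91. Of 11 iron homeostasis genes 5 were higher and 2 lower, and 5 and 3 adjusted over the list alone (camera adjusted p = 0.683), with NAS4 at 1.17, FER3 at -0.84 and BHLH101 at 0.79. BHLH100, above background on 3 of 4 wild-type arrays and on all 3 transgenic arrays with a value, had a change of 1.24 (n = 4 and 3) and of -0.21 with normexp. Of 17 ethylene genes 2 were higher and 3 lower, and 2 and 5 adjusted over the list alone (camera adjusted p = 0.674), with PR4 at 1.15, ETR2 at -1.01 and EBF2 at -0.53. The other ETR2 probe did not pass (-0.42, adjusted p = 0.607). ERF2 at -0.28 was chosen after its value was seen. Of 18 calcium, touch and early elicitor genes 1 was higher and 3 lower, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.373), with PHI-1 at -2.87, TCH4 at -1.74, FRK1 at 0.92 and RAV1 at -0.53. BHLH100, BHLH101, FRK1, RAV1 and TCH4 lost the call in 6, 4, 7, 5 and 1 of the 8 fits that left out 1 array. NAS4, BHLH101, PHO1;H1, ETR2, TCH4, FRK1 and RAV1 lost it with normexp.

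Of 18 oxidative stress and antioxidant genes 4 were higher and 2 lower, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.674), with CAT2 at 0.72, 2CPB at 0.64, CSD2 at -1.06 and CSD1 at -0.87. FSD1 at 0.59 and PRXIIE at 0.30 were chosen after their values were seen. Of 12 heat shock genes 3 were higher and 1 lower, and as many adjusted over the list alone (camera adjusted p = 0.919), with BIP3 at 1.35, HSFA7A 1.99-fold lower, HSP18.2 at 0.83 and ROF2 at 0.52. Of 13 flowering time genes 0 were higher by limma and 2 lower, and 0 and 1 adjusted over the list alone (camera adjusted p = 0.586), with FUL at -0.70 and CO, above background on 1 of 4 transgenic arrays, at -2.37. Of 4 reference genes 1 was higher, GAPC2 at 0.32, and 1 adjusted over the list alone (camera adjusted p = 0.854), and GAPC2 did not pass with median scaling (0.23, adjusted p = 0.0548). CSD1, CSD2, HSP18.2, ROF2 and FUL lost the call in 6, 3, 2, 2 and 7 of the 8 fits that left out 1 array, and the other FUL probe did not pass (adjusted p = 0.098). CSD1, CSD2, BIP3, HSP18.2, ROF2, FUL, CO and GAPC2 lost it with normexp.

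Other probes of some named genes passed in the same direction with another size. They changed by 0.82 for SEP3, -0.84 for GA2OX2, 0.49 for GH3.5, 3.41 for P5CS1, 1.94 to 3.51 for PYK10, and 2.55 and 3.87 for JAL33. With quantile normalization and with the deposited value table, 1 root marker was higher, 1 guard cell marker and 1 trichome marker were lower, 2 heat shock and 2 phosphate starvation genes were lower, and 0 calcium, touch and early elicitor genes were higher by limma. Without transgenic replicate 1, 1 root marker, 1 ethylene gene and 0 calcium, touch and early elicitor genes were higher, and 1 trichome marker, 1 flowering time gene, 1 oxidative stress gene, 1 abscisic acid gene and 2 salicylic acid genes were lower.

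In all, 9 of 31 lists passed camera with the preset correlation, 8 higher and 1 lower, and the same 9 passed with slide as a fixed block and without transgenic replicate 1. Without that array 13 cold and CBF regulon members were lower, and 12 flavonoid, 9 chlorophyll, 8 indole glucosinolate, 2 aliphatic glucosinolate, 8 abscisic acid, 10 cuticle and 7 salicylic acid members were higher. With an estimated correlation camera called 0 lists, 1 list had an unadjusted p under 0.05, and fry called 20. Other splits of the 8 arrays into 4 and 4 gave as many lists in 7 of 34 cases, with a highest count of 11, and gave at most 1 gene. Of these 7, 6 kept 3 arrays of a genotype together and so still carried part of the genotype difference. Median, mean and camera direction differed in sign for the ethylene, gibberellin, oxidative stress, heat shock, trichome and reference lists, with medians of -0.15, 0.08, -0.02, -0.04, -0.01 and -0.03. With a floor on dim values the ethylene median was 0.02 and 5 members were lower. With quantile normalization the gibberellin, oxidative stress and reference medians also changed sign, to -0.009, 0.0004 and 0.005.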

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

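The tests of the RAP2.9 probes, of the CBF genes, of the scaling and of the dim signals on transgenic replicate 1 were chosen only after the result was seen, and the tests of splits and harvest time were not. The harvest time test does use the same morning and evening clock genes as a comparison of clock phases that was chosen afterwards.

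The 4 arrays of a genotype were compared in 277 groups of values, counted over both genotypes. In 14 of them 1 array lay far from the other 3, with a gap, as a share of the whole range, past the 95% critical value of Dixon's test. Chance alone gives about 5% of such groups, which is about as many as were found. LTP4 was at -1.83 on wild-type replicate 4 and between -4.48 and -4.25 on the others (gap 0.913 of the range). SAG12 was at -0.69 on transgenic replicate 2 and between -5.68 and -4.90 on the others (0.845). AT1G53633 was at -5.21 on transgenic replicate 1 and between -6.29 and -6.13 on the others (0.855). LTI30 was at 2.62 on wild-type replicate 2 and between 2.201 and 2.203 on the others (0.994). BZS1 was at -5.29 on transgenic replicate 1 and between -5.95 and -5.85 on the others (0.849). RAP2.1 was at -1.36 on transgenic replicate 4 and between -1.31 and -1.30 on the others (0.892). EBF2 was at 1.23 on wild-type replicate 1 and between 1.36 and 1.39 on the others (0.841). CER4 was at -2.08 on transgenic replicate 2 and between -2.99 and -2.84 on the others (0.842). PHS1 was at 4.49 on transgenic replicate 2 and between 4.69 and 4.72 on the others (0.879). PPCK1 was at -1.52 on transgenic replicate 3 and between -1.27 and -1.24 on the others (0.891). PHO1;H1 was at -4.03 on wild-type replicate 1 and between -4.76 and -4.66 on the others (0.852). BHLH100 was at -7.44 on wild-type replicate 2 and between -6.48 and -6.32 on the others (0.864). The 75th percentile of the signal was 1699 on transgenic replicate 2 and 2562 to 2576 on the others (0.984). The 5th percentile was 16.3 on transgenic replicate 1 and 3.68 to 5.37 on the others (0.866).

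The last of these belongs to a wider pattern, in which dim gene probes had a raw median signal of 113 on transgenic replicate 1 and 35 to 44 on the other arrays. These 6989 probes were chosen as not well above background on any other array, with no such limit on transgenic replicate 1. That choice enlarges the excess by an unknown amount. Negative control spots were raised by 40% as much as dim gene probes, a share that the choice lowers. A higher background common to all spots is still argued against, since negative control spots were raised by 29 and the 3 dimmest spike-in probes by 156. Labelled material from the RNA sample alone is argued against as well. The 3 dimmest spike-in probes, which that sample does not feed, were raised by 215% as much as dim gene probes. What raised these signals stays open, and no biological explanation was tested. Among the dimmest 5018 genes 601 were higher and 248 lower, and without that array 500 were higher and 532 lower.

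The number of changed genes was larger than other groupings of the arrays gave: 1 of the 35 splits into 4 and 4, the real one, gave 8685 genes. The highest other split gave 1. Ranking first of 35 splits is the most this test can show, so by itself it cannot exclude chance. The other splits also mix the genotypes in a group, so the difference between genotypes widens the spread and lowers their counts. For the gene lists chance cannot be excluded either. Of the 35 splits, 8 gave at least the 9 lists of the real one, and the highest other gave 11. Of the 7 others, 6 were among the 16 splits that kept 3 arrays of a genotype together. Those splits still carry part of the genotype difference, so their counts do not measure chance alone. The remaining 1 was among the 18 splits with 2 arrays of each genotype on both sides, where the highest count was 9. The split by slide gave 1 list and 0 genes by limma.

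The fall of the cold and CBF regulon beside a rise of CBF3 was weighed next. Lower CBF transcript levels at harvest are argued against only for CBF3, which rose past the threshold. The median log2 change of CBF1, CBF2 and CBF3, 0.76, was that of CBF1, which did not pass. CBF2 did not pass either, and levels before harvest were not measured. The scaling between arrays is argued against, since the list median stayed below that of all genes under 6 scalings, with -1.51 nearest to 0. Of these, 3 shift all genes of an array alike and cannot move this difference. Quantile normalization and the deposited value table gave nearly the same value, -1.571 and -1.565, and are not separate support. A difference in the time of day at harvest cannot be told apart from the genotype. The slope of the list mean without CBF genes on the morning minus evening clock level, within genotypes, predicts a shift of -0.17. Its 95% interval, from -1.36 to 1.02, leaves out the observed fall of -2.38. The test cannot decide, since the slope rests on clock levels with an SD of 0.16 and 0.17 (n = 4 each) and is carried over a difference of 1.41. Arrays of a genotype also need not differ in harvest hour. A direct or indirect effect of the overexpressed factor may account for the fall and was not tested.

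The opposite changes of the 2 RAP2.9 probes were weighed last. A falling probe too dim or too bright to follow its transcript is argued against, since it was above background and unsaturated on 8 of 8 arrays. Signal from related transcripts cannot be told apart from RAP2.9 signal: the probe fell by no more than RAP2.1, with an excess of -0.0876 standard errors, and DEAR3 changed by -1.71, while RAP2.10 at -1.30 and DEAR1 at -0.99 fell less, by 1.97 and 2.9 standard errors. The probe may instead read a part of the native transcript that the transgene lacks, such as an untranslated region, and without probe sequences this was not tested.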

How the results depend on the processing

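The normexp signal column, the floor on dim values and the list counts without transgenic replicate 1 were tests chosen only after the result was seen, and the others were planned. The log2 change of the brighter RAP2.9 probe was past the threshold as higher under every alternative run on it. The mean of both probes gave 1.18, the other probe on its own was past the threshold as lower at -1.77, and the brighter probe had a range of 4.04 to 4.22 when each array was left out. Leaving out each array gave 3525 to 4342 higher and 3022 to 4013 lower genes, and 7 to 11 lists. Normexp gave 1285 higher and 1499 lower genes. Its offset of 50 shrinks the log2 changes of dim genes by construction, and how much of the smaller counts comes from it was not tested. Replicate number together with slide as blocks gave 2762 and 1875, with fewer degrees of freedom left for the spread. The stricter adjusted p of 0.01 gave 2390 and 2144, and a log2 change of at least 1 gave 1046 and 578. Both are smaller by construction.

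Replicate number alone as a block gave 4021 and 2971. Correlations of paired deviations were 0.155, -0.0923, -0.323 and 0.275, and 2 of 4 wild-type arrays matched best with their own number. So few arrays, with those of the same number always on different slides, cannot show whether the numbers pair them. Testing every probe on its own gave 16 lists, with 7 gained (flower organ, guard cell, jasmonate, phloem, phosphate starvation, photosynthesis and root), and the cause was not tested. Camera with an estimated correlation gave 0 lists (1 at an unadjusted p under 0.05), and fry gave 20 in a single direction and 27 in either, as fry does not compare a list with other genes. List tests were not run with slide as a random block. The change of BHLH100 reversed to -0.21 (adjusted p = 0.956) with normexp, and the cause was not tested. Of 133 named genes under normexp, 74 kept their call or lack of one and 58 lost it. With slide as a fixed block 124 kept it and 9 lost it, and with replicate number and slide 104 and 29. Of 134 named genes, 25 lost the call in at least 1 fit that left out an array. The median change of all genes was 0.03 and moved to 0.13 with no filter on dim probes. Signal over background set which genes could be tested, and 10456 probes fell below the filter.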

Other observations

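The tests of symbol families and of clock phases were chosen only after the result was seen, and so were the genes named in this part.

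Genes of fasciclin-like arabinogalactan proteins (FLA), which sit in the cell wall, moved both ways, with 7 of 12 lower and 1 higher. FLA15 (AT3G52370) fell by 2.56 ± 0.29 (SE, n = 4 per genotype), FLA13 (AT5G44130) by 2.33 ± 0.11 (SE) and FLA9 (AT1G03870) by 1.95 ± 0.12 (SE), while FLA11 (AT5G03170) rose by 0.89 ± 0.23 (SE). Of 14 genes grouped only by the SAUR prefix, a name for genes that auxin induces, 9 were higher and 0 lower by limma. Among them SAUR15 (AT4G38850) rose by 1.36 ± 0.19 (SE) and SAUR68 (AT1G29510) by 0.97 ± 0.15 (SE). Whether every gene with the SAUR prefix belongs to that family was not checked. Of 48 receptor-like protein genes (RLP), 24 were higher and 5 lower, with RLP7 at 1.24 and RLP33 at -2.10. Without transgenic replicate 1 these counts were 19 and 5. Of 29 genes with the CRK prefix, most of them cysteine-rich receptor-like kinases, 13 were higher and 4 lower, with CRK23 at 1.32 and CRK42 at -1.68.

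Of 143 symbol families screened with camera, 2 passed, SAUR (adjusted p = 0.00982) and RLP (adjusted p = 0.03), and both had an adjusted p of 0.895 with an estimated correlation. For this number chance cannot be excluded, since 28 of 35 splits gave as many families and the highest other gave 13.

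Of 9 clock genes that peak in the morning 8 were higher, with a median of 0.87, and of 6 that peak in the evening 4 were lower, with a median of -0.51. The difference between morning and evening levels was -5.22 ± 0.16 (SD, n = 4) in the wild type and -3.81 ± 0.17 (SD, n = 4) in the transgenic leaves, a shift of 1.41. The hour of harvest is not given in the sources used here.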
